A study of Sus scrofa with 59 samples.

How the data were processed

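Total RNA from the longissimus dorsi muscle of 59 pigs was extracted, converted to biotin-labelled cRNA and hybridised to Affymetrix porcine arrays, 1 array per pig, per the labels' protocols. The pigs came from a cross that the labels name LD/LW x Duroc, were raised together and were 170 days old. Muscle was frozen in liquid nitrogen at slaughter, per the labels. The labels mention 33 traits of composition, conformation and meat quality, whose values per pig were not analysed here, and they give no sex and no array batch per pig. All 59 arrays therefore formed 1 group, and the pig number in each title only names the array.

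The deposited table holds 1 normalised value per probe set and array, on what was taken to be the log2 scale. The submitters' processing notes name GCRMA, a method that corrects background by probe sequence, normalises by quantiles and summarises probes, and its version is not given in the sources used here. The log base is not given in the sources used here either: values between 2.39 and 15.04 with array medians from 6.23 to 6.30 were read as log2. GCRMA sets signals near background to similar low values, so differences of dim genes are compressed. The brightest genes lie near the top of the range, which also compresses their differences. Fold sizes derived from these values are relative to that scale. No count of molecules lies behind an array value, and only the number of arrays sets the precision.

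The 24123 probe sets included 124 controls. A platform annotation table gave 1 gene symbol for 10099 probe sets, several for 198 and none for 13826. Probe sets with several symbols or none were tested but not named. Symbols were updated through the Entrez identifier for 9989 probe sets and kept as given for 110, which left 6765 distinct genes. No genome positions are printed, since the annotation table gives none. Probe sets with a mean over all arrays at or above the median of all means (6.27 log2) were tested, 12000 in all with 4928 genes. Where a gene had several tested probe sets, the one with the highest mean stood for it. No 2 arrays held identical values.

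There were 28 fixed gene lists with 490 genes, of which 347 were on the array and 314 passed the filter, with 12 older symbols matched by hand. A further mixed list of 20 meat quality candidates, 15 of them measured, is not part of these counts. The 28 lists cover adipocyte markers, lipogenesis, triglyceride synthesis and lipolysis, fatty acid oxidation, oxidative phosphorylation, the TCA cycle, glycolysis, glycogen metabolism, slow fibre, fast fibre, calcium handling, extracellular matrix, immediate early genes, heat shock, hypoxia and metallothionein, proteolysis and atrophy, proteasome, ribosomal proteins, cholesterol synthesis, myogenic regulation and the circadian clock. Markers of other cell types were macrophage and leukocyte, interferon response, red blood cell, endothelial, smooth muscle and pericyte, and nerve and Schwann cell. A list of X inactivation and Y-linked genes had 1 measured gene, EIF1AY. A list's score was the mean of its measured genes' log2 values, each standardised over the 59 arrays, and was then scaled to an SD of 1.

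Spread was described by the SD over arrays with 95% intervals from 1000 bootstrap resamples of the arrays. Whether a list's genes varied together was measured by the median Pearson r over all pairs of its genes, for the 25 lists with at least 4 measured genes, leaving out the mixed list of meat quality candidates, against 10000 random lists of the same size matched on mean expression. Correlations between scores were computed for 20 fixed pairs, with Pearson's r and Spearman's rho, two-sided permutation tests of 100000 resamples each and Benjamini-Hochberg adjustment over the 20. Each was repeated without the 2 arrays farthest from the median of the former score. The slope of every probe set per SD of the adipocyte, slow fibre, oxidative phosphorylation and immediate early scores was fitted with limma (lmFit and eBayes) on log2 values, leaving out all probe sets annotated by symbol to the score's own genes, and p-values were adjusted by Benjamini-Hochberg over the probe sets tested, with a threshold of 0.05. Probe sets with no symbol or several could not be left out in this way. Counts of probe sets that followed a score may therefore include some that measure its own genes. Lists were tested with camera with a preset correlation and with one estimated from the residuals. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

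Named genes followed a fixed rule. It took the 15 genes with the highest SD and the 5 with the lowest SD among the 6000 brightest probe sets. For each score it took the 10 genes with the largest positive and the 10 with the largest negative slopes among those past the threshold that kept their sign and an unadjusted p under 0.05 without the 2 extreme arrays. It also took up to 6 members per list by lowest p, and the meat quality candidates. The meaning of an abbreviated breed name was not guessed, and a sex was not inferred from expression.

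The regression was tested on simulated data, with the values of each real probe set shuffled over the arrays and slopes planted in 200 probe sets per score. Shuffling removed the correlation between probe sets. The shares recovered and the false calls therefore describe independent probe sets and may differ in the real data. For the adipocyte score (11996 probe sets) 56.7% of slopes of 0.1 log2, 86.6% of 0.2 and 98.5% of 0.4 were recovered, with 12 false calls. For the slow fibre score (11986 probe sets) the shares were 44.8%, 83.6% and 100%, with 14 false calls. For the oxidative phosphorylation score (11962 probe sets) they were 61.2%, 94.0% and 100%, with 0 false calls, and for the immediate early score (11984 probe sets) 50.7%, 92.5% and 98.5%, with 8. With 59 arrays, a correlation of 0.3 had an unadjusted permutation p under 0.05 in 63 of 100 simulated draws, one of 0.5 in 99 and one of 0 in 4. The correlations reported below had to pass after adjustment over 20 pairs, which can only lower these shares. The test of lists, also run on shuffled values, called 20 of 20 planted lists and 1 of 20 unplanted ones over 4928 genes. The planted lists all had the same size and a pairwise r of 0.3. Weaker correlation and other list sizes were not tried, so a list that did not pass may still vary together.

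Alternatives were the filter on dim probe sets, re-centring or quantile normalisation of the arrays, the way a score is formed, the choice of probe set, ranks in place of values, odd-numbered or even-numbered pigs alone, each array left out in turn, and covariates. The covariates were the first principal component of tested probe sets in no list (20.2% of their variance), the mean standardised 3' minus 5' difference of the array's control probe sets, the other 3 scores and, added after the data had been seen, the EIF1AY level. Lists were matched by gene symbol, so the component also drew on probe sets with no symbol or several. Some of these may measure listed genes.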

Results

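Gene expression was measured in the longissimus dorsi, the long back muscle, of 59 crossbred pigs at 170 days of age, with 1 array per pig. The study set out to relate muscle expression early after slaughter to carcass composition and meat quality. The labels used here give 1 group of pigs and neither a trait value nor the sex of any pig, so no groups and no traits were compared. The comparisons below ask how far genes varied between pigs, which gene groups varied together, and which genes followed 4 gene list scores. The array held 24123 probe sets, of which 12000 with a mean at or above the median were tested, and these covered 4928 genes. Deposited values ran from 2.39 to 15.04 on the log2 scale, array medians from 6.23 to 6.30, and the correlation between any pair of arrays from 0.969 to 0.995. The number of arrays limits the precision of every value.

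Most genes varied little between pigs, and a small set varied by several log2 units. SPP1, which encodes the secreted phosphoprotein osteopontin, averaged 8.27 ± 2.63 log2 (SD, n = 59) and ran from 4.35 to 12.95. The interferon-induced chemokine CXCL9 averaged 7.41 ± 1.74 (SD, n = 59), and GBP1, an interferon-induced guanylate binding protein, averaged 8.66 ± 1.56 (SD, n = 59). Immediate early genes, which are transcribed within minutes of a stimulus, were also among the 15 genes with the largest spread: NR4A3 with an SD of 1.31, EGR1 with 1.15, ATF3 with 1.11 and FOS with 1.08. FOS ran from 8.85 to 13.20. HSPA6, an inducible member of the HSP70 family, averaged 8.12 ± 1.30 (SD, n = 59), and 1 pig at 13.60 stood 2.37 above the next pig at 11.22.

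The other genes among the 15 were EIF1AY (SD 3.49), the pigmentation gene OCA2 (2.00), the paraoxonase gene PON3 (1.78), LOC396781 (1.33), the protease inhibitor gene SLPI (1.11), the antioxidant enzyme gene GPX1 (1.07) and GPNMB (1.06). The values of EIF1AY and OCA2 lay in separate clusters, so their SD does not describe a single distribution. The 5 probe sets of GPNMB disagreed, with correlations to the brightest one from -0.370 to 0.946. Over all 4928 genes the median SD was 0.197 log2, 217 genes had an SD of at least 0.5 and 19 had an SD of at least 1. Both limits were chosen after the spreads had been seen. Among the 6000 brightest probe sets alone, 12 genes reached an SD of 1. The smallest spreads among bright genes were those of ACTG1 (0.014), GAPDH (0.021), the fast troponin gene TNNC2 (0.029), the muscle creatine kinase gene CKM (0.030) and YBX3 (0.031), all with means above 14 log2, near the top of the range of values. Each SD is that of the brightest probe set. Other probe sets correlated with it at 0.042 to 0.218 for ACTG1, -0.197 to 0.636 for GAPDH and -0.212 for YBX3.

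**Figure D1:**
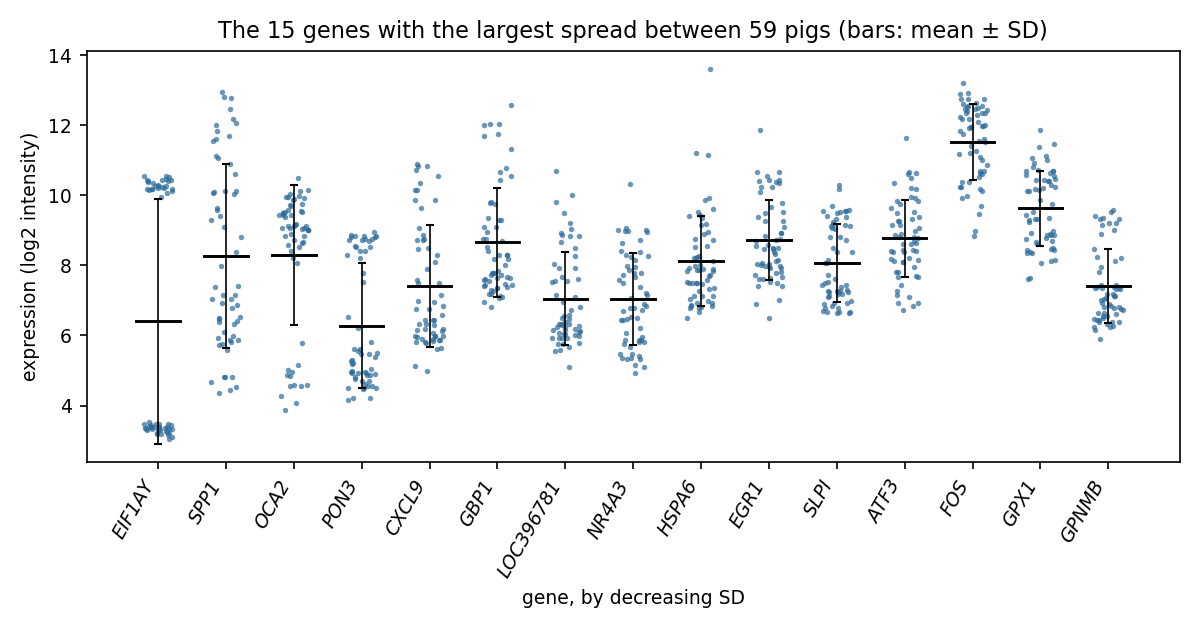
Expression on the log2 scale of the 15 genes with the largest SD, with 1 point per pig (n = 59) and black bars for the mean ± SD. EIF1AY has 33 pigs at or below 3.52 and 26 at or above 9.97, and HSPA6 has 1 pig at 13.60.

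Genes of the contractile, mitochondrial and stress lists varied together between pigs. The slow fibre genes had a median pairwise r of 0.799 (95% interval 0.688 to 0.858, 9 genes), the heat shock genes 0.763 (0.690 to 0.822, 15 genes) and the macrophage and leukocyte genes 0.744 (0.656 to 0.803, 11 genes). Of the 9 slow fibre genes, TPM3 and CA3 hardly followed the rest, with correlations of -0.0125 and 0.157 to the mean of the others. The lowest value among the remaining genes was 0.843, for ATP2A2. The slow fibre value was 0.379 without the filter on dim genes, which adds CASQ2 alone, and 0.516 with the mean of all probe sets of a gene. The heat shock genes (0.763 and 0.670) and the macrophage genes (0.615 and 0.699) were then above it. Fast fibre genes reached 0.614, immediate early genes 0.602, oxidative phosphorylation genes 0.578, extracellular matrix genes 0.547, interferon response genes 0.532, proteasome genes 0.521, ribosomal protein genes 0.478 and TCA cycle genes 0.452. Values were lower for smooth muscle and pericyte genes (0.367), fatty acid oxidation (0.356), glycolysis (0.352), endothelial genes (0.310), the circadian clock (0.199) and glycogen metabolism (0.167). These 17 of the 25 lists tested exceeded random lists of the same size and expression level at an adjusted p under 0.05. The adjusted p was 0.000192 for each list at the smallest p that 10000 random lists can give (0.0001), and 0.000714, 0.0055, 0.0144 and 0.0381 for the endothelial, smooth muscle, glycogen and circadian lists. Other calls were kept at values over 1.5 times apart: fast fibre at 0.408 and ribosomal proteins at 0.304 with the mean of all probe sets, endothelial genes at 0.201 without the filter, heat shock at 0.484 with the first principal component removed and glycogen at 0.303 in even-numbered pigs.

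The remaining 8 lists did not pass. Their median pairwise r was 0.185 for adipocyte genes (adjusted p = 0.0611), 0.171 for lipogenesis (0.0501), 0.109 for cholesterol synthesis (0.0501), 0.046 for myogenic regulation (0.23), 0.044 for proteolysis and atrophy (0.241), 0.016 for triglyceride synthesis and lipolysis (0.351), -0.032 for hypoxia and metallothionein (0.654) and -0.058 for calcium handling (0.692). Among alternatives, the adipocyte list passed when all its named members were used (median r = 0.306, adjusted p = 0.000579), which adds the dimmer ADIPOQ, RBP4, RETN and PPARG. It also passed with Spearman correlations (adjusted p = 0.0487), the mean of all probe sets (0.00983), quantile normalisation (0.0424) and in odd-numbered pigs (0.0439), but not in even-numbered pigs (0.111) or with the first principal component removed (0.135). Lipogenesis passed with Spearman correlations (adjusted p = 0.0208) and in even-numbered pigs (0.046). Cholesterol synthesis passed with Spearman correlations (adjusted p = 0.0384), quantile normalisation (0.0424) and in even-numbered pigs (0.0169), and proteolysis with the mean of all probe sets (0.0432). The circadian clock list lost its call without the filter on dim genes (adjusted p = 0.0519), with the mean of all probe sets (0.0654), with the first principal component removed (0.129) and in the odd-numbered pigs (0.427). The smooth muscle list lost its call without the filter on dim genes (median r = 0.112, adjusted p = 0.121) and the glycogen list in the odd-numbered pigs (median r = 0.114, adjusted p = 0.0762).

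**Figure D2:**
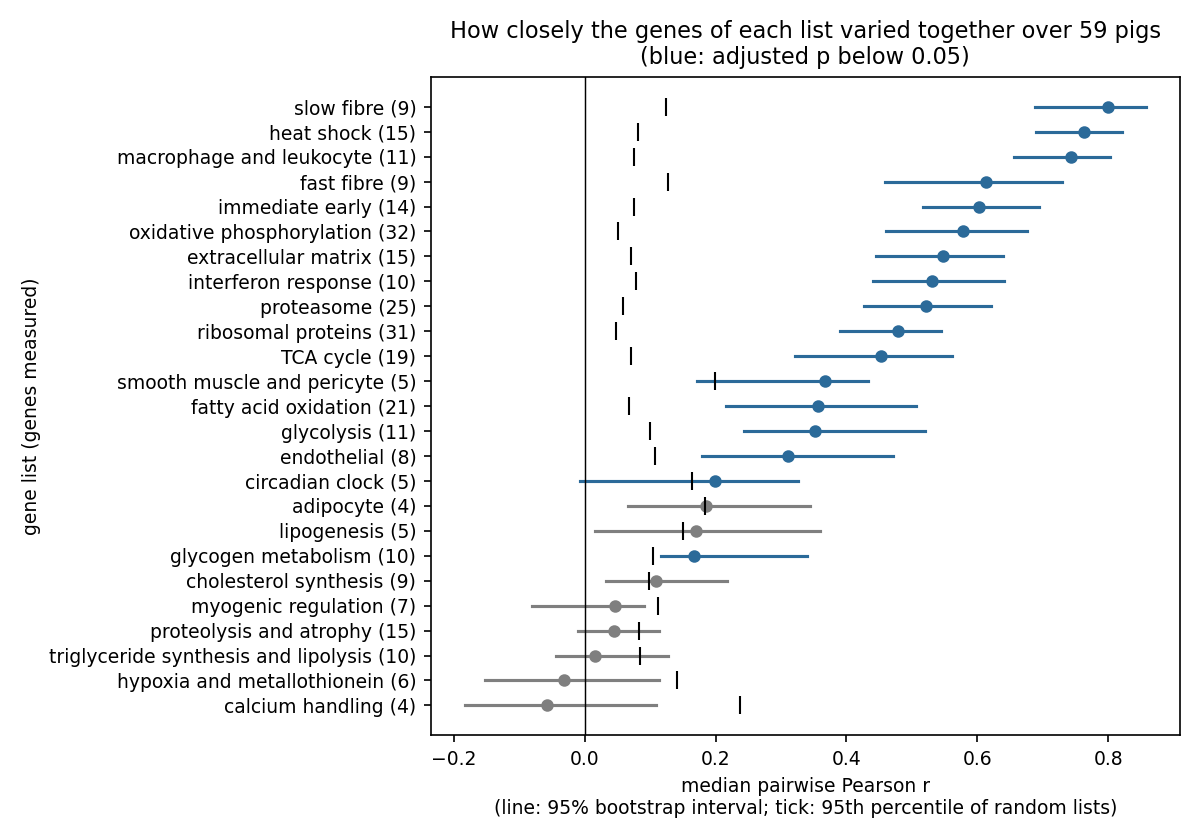
Median pairwise Pearson r of the genes of each list over 59 pigs, with 95% bootstrap intervals as lines and the 95th percentile of random lists as black ticks. In this setting slow fibre genes lie highest at 0.799, against 0.379 without the filter on dim genes, and calcium handling genes lowest at -0.058.

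Fast fibre and glycolytic expression rose and fell together, as did oxidative phosphorylation and TCA cycle expression. The fast fibre score correlated with the glycolysis score at r = 0.849 (n = 59, permutation p = 1e-05, adjusted p = 5e-05), with rho = 0.787 (p = 1e-05, adjusted p = 0.0001). The differences behind these standardised scores were small. From the lowest to the highest pig, the mean of the fast fibre genes spanned 0.36 log2 and that of the glycolysis genes 0.39. The fast fibre genes averaged 14.27 log2, near the top of the range, where differences are compressed. The oxidative phosphorylation score correlated with the TCA cycle score at r = 0.810 (permutation p = 1e-05, adjusted p = 5e-05), with rho = 0.794 (p = 1e-05, adjusted p = 0.0001). A p of 1e-05 is the smallest that 100000 resamples can give, and all 20 correlations form 1 family for the adjustment. Slow fibre expression was higher in pigs with higher fatty acid oxidation (r = 0.615, permutation p = 1e-05, adjusted p = 5e-05, rho = 0.570, p = 2e-05, adjusted p = 0.000133). It was also higher in pigs with higher oxidative phosphorylation (r = 0.525, permutation p = 3e-05, adjusted p = 0.00012, rho = 0.489, p = 0.00016, adjusted p = 0.00064). Without the 2 pigs farthest from the median of the former score, these 4 correlations were 0.795, 0.741, 0.498 and 0.422. The slow and fast fibre scores were negatively related (r = -0.425, permutation p = 0.00108, adjusted p = 0.0027), but rho was -0.258 (p = 0.0487, adjusted p = 0.0886). The value was -0.209 (adjusted p = 0.172) without the 2 extreme pigs and -0.243 (adjusted p = 0.11) without pig 72 alone, so the call over all pigs rests on them. In the 27 odd-numbered pigs r was -0.502 (adjusted p = 0.0286) and in the 32 even-numbered pigs -0.383 (adjusted p = 0.0682).

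Oxidative phosphorylation was lower in pigs with higher ribosomal protein expression (r = -0.361, permutation p = 0.00484, adjusted p = 0.00968, rho = -0.314, p = 0.0157, adjusted p = 0.0315). Without the 2 extreme pigs this r was -0.295 (adjusted p = 0.0651), and with arrays re-centred on their medians it was -0.147 (adjusted p = 0.38). It was -0.220 (adjusted p = 0.359) in odd-numbered pigs. Oxidative phosphorylation and glycolysis gave r = -0.290 (permutation p = 0.0261, adjusted p = 0.0435) and rho = -0.182 (p = 0.164, adjusted p = 0.219). The value was -0.163 (adjusted p = 0.282) without the 2 extreme pigs, -0.458 (permutation p = 0.0158, adjusted p = 0.0526) in odd-numbered pigs and -0.206 (adjusted p = 0.394) in even-numbered pigs. Leaving out any 1 of pigs 1, 10, 15, 16, 19, 31, 41, 47, 50, 52, 59, 66, 71 and 72 ended this call, with r between -0.382 and -0.106 over all pigs left out in turn. Slow fibre and calcium handling scores did not pass (r = 0.087, permutation p = 0.513, adjusted p = 0.54, rho = 0.207, p = 0.116, adjusted p = 0.165, r = 0.258 without 2 pigs). With the first principal component of each list, whose sign is arbitrary for calcium handling, r was -0.672 (adjusted p = 2.86e-05).

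Adipocyte expression was higher in pigs with higher lipogenic and extracellular matrix expression. The adipocyte score correlated with the lipogenesis score at r = 0.544 (n = 59, permutation p = 1e-05, adjusted p = 5e-05, rho = 0.506, p = 7e-05, adjusted p = 0.00035). It correlated with the extracellular matrix score at r = 0.503 (permutation p = 9e-05, adjusted p = 0.0003, rho = 0.450, p = 0.00032, adjusted p = 0.00107). Without the 2 extreme pigs these were 0.460 and 0.481. Neither passed in the 27 odd-numbered pigs (r = 0.298, adjusted p = 0.218, and r = 0.401, adjusted p = 0.111), and both did in the 32 even-numbered pigs (0.708 and 0.584). Lipogenesis and cholesterol synthesis gave r = 0.383 (permutation p = 0.0028, adjusted p = 0.00622, rho = 0.353, p = 0.00626, adjusted p = 0.0156), and 0.278 (adjusted p = 0.0809) without the 2 extreme pigs. That call also ended in odd-numbered pigs (0.140, adjusted p = 0.571) and with all named members (0.218, adjusted p = 0.163). The adipocyte score did not pass with the macrophage and leukocyte score (r = 0.228, permutation p = 0.0815, adjusted p = 0.116, rho = 0.245, p = 0.0605, adjusted p = 0.0981, r = 0.257 without 2 pigs), but it did with the first principal component of each list (0.384, adjusted p = 0.0047). Nor did it with oxidative phosphorylation (r = -0.109, permutation p = 0.411, adjusted p = 0.514, rho = -0.104, p = 0.433, adjusted p = 0.433, r = -0.085 without 2 pigs). It did not pass with fatty acid oxidation (r = 0.095, permutation p = 0.476, adjusted p = 0.54, rho = 0.106, p = 0.426, adjusted p = 0.433, r = 0.118 without 2 pigs). The pair of adipocyte with triglyceride synthesis and lipolysis did not pass (r = 0.092, permutation p = 0.49, adjusted p = 0.54, rho = 0.113, p = 0.393, adjusted p = 0.433, r = 0.080 without 2 pigs), but the partial correlation given the first principal component of probe sets in no list did (0.286, adjusted p = 0.0494). Extracellular matrix and endothelial scores gave r = 0.144 (permutation p = 0.279, adjusted p = 0.373, rho = 0.178, p = 0.178, adjusted p = 0.222, r = 0.093 without 2 pigs).

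Immediate early expression was higher in pigs with higher heat shock expression (r = 0.427, n = 59, permutation p = 0.00082, adjusted p = 0.00234, rho = 0.360, p = 0.00519, adjusted p = 0.0148, r = 0.324 without 2 pigs). Given the first principal component of probe sets in no list, the partial correlation was -0.077 (adjusted p = 0.592). That component itself followed the heat shock score (r = 0.851), so a low partial correlation was partly set by this choice. In odd-numbered pigs r was 0.273 (adjusted p = 0.259). Immediate early and proteolysis scores gave r = 0.294 (permutation p = 0.0241, adjusted p = 0.0435, rho = 0.318, p = 0.0148, adjusted p = 0.0315) and 0.250 (adjusted p = 0.1) without the 2 extreme pigs. That call ended without any 1 of pigs 1, 31, 36, 37, 41, 43, 45, 46, 47, 50, 52, 60 and 66, with r from 0.255 to 0.349 over all pigs left out in turn. Immediate early and hypoxia scores did not pass (r = 0.253, permutation p = 0.053, adjusted p = 0.0815, rho = 0.242, p = 0.0638, adjusted p = 0.0981, r = 0.208 without 2 pigs). They did without pig 40 or pig 72, with a highest r of 0.356. They also passed with the first principal component of each list (r = 0.560, adjusted p = 2.86e-05) and with the mean of all probe sets (r = 0.456, adjusted p = 0.0007), while r was 0.102 (adjusted p = 0.523) with all named members. Immediate early and circadian clock scores gave r = 0.061 (permutation p = 0.645, adjusted p = 0.645, rho = 0.171, p = 0.195, adjusted p = 0.23, r = 0.173 without 2 pigs), and passed given the first principal component (partial r = 0.374, adjusted p = 0.0083). In all, 12 of the 20 correlations passed, 9 positive and 3 negative.

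**Figure D3:**
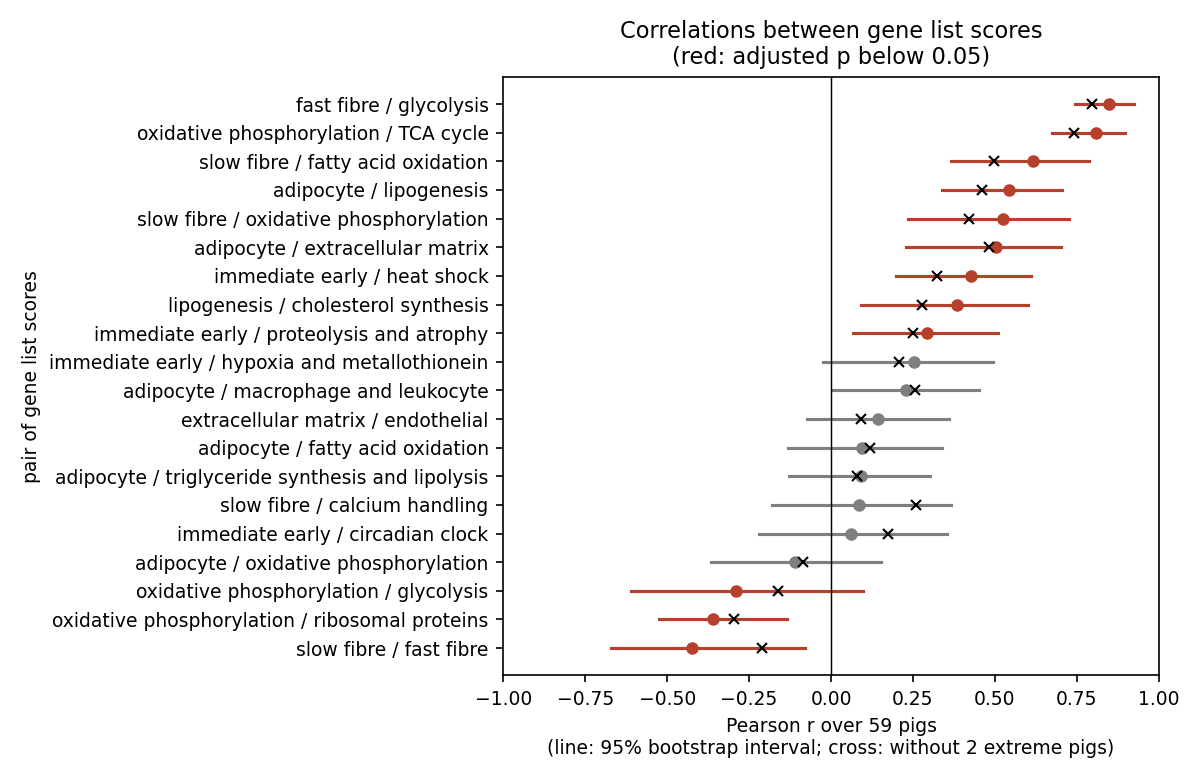
Pearson r between the scores of 20 pairs of gene lists over 59 pigs, with 95% bootstrap intervals as lines, pairs that passed in red and crosses for r without the 2 extreme pigs. The fast fibre and glycolysis pair lies highest at 0.849 and the slow and fast fibre pair lowest at -0.425.

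Which genes followed the adipocyte score was asked because intramuscular fat was among the traits the study recorded. Of 5 lipogenesis genes 2 were higher in pigs with a higher score, and triglyceride genes went both ways. ELOVL6, a fatty acid elongase, was higher by 0.33 ± 0.05 log2 per SD of the score (SE, n = 59, limma adjusted p = 1.05e-05). DGAT2, which catalyses the last step of triglyceride synthesis, was higher by 0.29 ± 0.06 (adjusted p = 0.00212) and the fatty acid synthase gene FASN by 0.21 ± 0.06 (adjusted p = 0.00856). Of 15 extracellular matrix genes 11 were higher as well, among them FN1 for fibronectin (0.23 ± 0.06), FBN1 for fibrillin (0.16 ± 0.03), the proteoglycan genes BGN (0.16 ± 0.04) and DCN (0.13 ± 0.03), SPARC (0.11 ± 0.03) and COL6A2 (0.09 ± 0.02), with adjusted p from 0.00134 to 0.00615. Of 15 heat shock genes 11 were lower, with HSP70.2 at -0.30 ± 0.05 (adjusted p = 5.07e-05), DNAJA1 at -0.30 ± 0.07 (0.00483), HSPH1 at -0.29 ± 0.06 (0.00116) and BAG3 at -0.24 ± 0.05 (0.000381). The score rested on FABP4, CFD, CIDEA and LEP, and the correlation of each with the mean of the others was 0.405, 0.414, 0.547 and -0.044.

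The largest positive slopes were those of MGST1, a microsomal glutathione transferase (0.44 ± 0.06, adjusted p = 1e-06), FBXL4 (0.33 ± 0.11), ELOVL6, RIPOR2 (0.33 ± 0.12), the serine synthesis gene PSAT1 (0.32 ± 0.06), PPP1R3B (0.32 ± 0.10), NRN1 (0.30 ± 0.11), the retinol saturase gene RETSAT (0.29 ± 0.05), DGAT2 and MYLIP (0.29 ± 0.06). The largest negative slopes were those of HSPA6 (-0.57 ± 0.15, adjusted p = 0.00733), NR4A3 (-0.54 ± 0.15), ATF3 (-0.46 ± 0.13), ANKRD1 (-0.45 ± 0.11), EGR1 (-0.43 ± 0.14), XIRP1 (-0.43 ± 0.11), RRAD (-0.39 ± 0.10), GADD45A (-0.38 ± 0.12), the AMP kinase subunit gene PRKAG2 (-0.38 ± 0.08) and TGFB2 (-0.35 ± 0.08). In total 1893 of 11996 probe sets passed, 704 higher and 1189 lower with the score. This balance depended on the setting: 951 were higher and 547 lower with the first principal component of the list as score, 344 and 338 with all named members, and 229 and 121 with the first principal component of probe sets in no list as a covariate. By 1 probe set per gene, 335 of 4924 genes were higher and 467 lower. Of 79 genes with several such probe sets 1 (PLBD1, named after its values were seen) had opposite signs.

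Of 15 extracellular matrix genes 11 were higher, none lower and 4 did not pass (12 higher when adjusted over the list alone). As a set they moved up (camera adjusted p = 5.13e-08, but adjusted p = 0.224 with an estimated correlation). Of 15 heat shock genes 11 were lower and 4 did not pass (15 lower when adjusted over the list alone, camera adjusted p = 7.26e-09, adjusted p = 0.224 with an estimated correlation). Of 25 proteasome genes 4 were lower, and the count was 4 when adjusted over the list alone (camera adjusted p = 0.00113, adjusted p = 0.823 with an estimated correlation). Lipogenesis had 2 of 5 higher (2 adjusted over the list alone, camera adjusted p = 0.00677, adjusted p = 0.224 with an estimated correlation). Immediate early genes had 3 of 14 lower (3 adjusted over the list alone, camera adjusted p = 0.0221, adjusted p = 0.897 with an estimated correlation). In the triglyceride list DGAT2 and PNPLA2 were higher, ABHD5 and LPIN1 lower, and 6 of 10 did not pass (also 2 and 2 adjusted over the list alone). In the myogenic list CHRNA1 (0.13 ± 0.03) and IGF1 (0.07 ± 0.02) were higher of 7, in the circadian list DBP of 5, in cholesterol synthesis FDFT1 of 9 and in proteolysis CTSK of 15. Adjusted over the list alone, those counts were 2 higher and 1 lower, 1, 1 and 1. Of 13 meat quality candidates outside the score, FASN was higher and PPARGC1A lower (-0.31 ± 0.10, adjusted p = 0.0364), also adjusted over the list alone. No member of the fatty acid oxidation, oxidative phosphorylation, TCA cycle, glycolysis, glycogen, slow fibre, fast fibre, calcium handling, hypoxia, ribosomal or interferon lists passed.

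Some markers of other cell types were also higher with the score. The smooth muscle and pericyte score correlated with the adipocyte score at 0.470 (95% interval 0.294 to 0.616, n = 59) and the endothelial score at 0.354 (0.155 to 0.569), beside 0.503 (0.225 to 0.709) for the extracellular matrix. The intervals held 0 for the nerve (0.223, -0.034 to 0.434) and interferon (0.054, -0.201 to 0.282) scores. For the macrophage score (0.228) whether 0 was held depended on the bootstrap draw, with intervals of -0.013 to 0.424 and 0.0069 to 0.450 from separate sets of 1000 resamples. Smooth muscle genes ACTA2 (0.21 ± 0.06) and RGS5 (0.11 ± 0.04) were higher of 5 (4 adjusted over the list alone, camera adjusted p = 0.0108, adjusted p = 0.224 with an estimated correlation). EGFL7 was higher of 8 endothelial genes (4 adjusted over the list alone, camera adjusted p = 0.0221, adjusted p = 0.47 with an estimated correlation). C1QA was higher of 11 macrophage genes (1 adjusted over the list alone, camera adjusted p = 0.0221, adjusted p = 0.897 with an estimated correlation). Of the nerve markers S100B and MBP neither passed, 1 did when adjusted over the list alone, and the red blood cell gene HBB did not. The first principal component of probe sets in no list correlated with the adipocyte score at r = -0.455 (permutation p = 0.00021, adjusted p = 0.00105, rho = -0.514, p = 7e-05, adjusted p = 0.000525, r = -0.445 without 2 pigs, 15 correlations in the family). The component also followed the heat shock score (r = 0.851), so as a covariate it may take out heat shock expression itself. With the component as a covariate, 350 probe sets passed, 1 of 15 heat shock genes was lower, and 6 of 15 extracellular matrix genes were higher. Of the 10 genes with the largest negative slopes 0 were then called and 9 kept their sign, and of the 10 with the largest positive slopes 5 were called and 8 kept their sign. FBXL4 (-0.034) and PPP1R3B (-0.022) turned negative and GADD45A (0.039) positive. The count of 1893 was 6 in the 27 odd-numbered pigs, 351 in the 32 even-numbered pigs, 682 with all named members in the score, 1015 with the other 3 scores as covariates and 1095 among the brightest 6000 probe sets, less those of the score.

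Which genes followed the slow fibre score was asked because fibre types differ in their metabolism. PLN, which encodes phospholamban, the regulator of the calcium pump of slow muscle, was higher by 0.42 ± 0.03 log2 per SD of the score (SE, n = 59, limma adjusted p = 2.68e-15). Of 21 fatty acid oxidation genes 11 were higher, among them lipoprotein lipase LPL (0.29 ± 0.06, adjusted p = 0.000712), ECI1 (0.19 ± 0.03, 2.37e-05), DECR1 (0.17 ± 0.03, 0.000254), ETFB (0.16 ± 0.03, 1.54e-05) and ACAA2 (0.16 ± 0.03, 3.6e-05). Hormone-sensitive lipase LIPE was higher (0.28 ± 0.06, adjusted p = 0.00347) as the only one of 10 genes of the triglyceride list. Of 32 oxidative phosphorylation genes 14 were higher, such as NDUFV1 (0.12 ± 0.02), NDUFA1 (0.09 ± 0.02) and NDUFA4 (0.08 ± 0.01), with adjusted p from 6.08e-05 to 8.3e-05. Of 9 fast fibre genes 3 and of 11 glycolysis genes 2 were lower, among them the glycolytic gene PGAM2 at -0.08 ± 0.02 (adjusted p = 0.00155) and the fast troponin gene TNNT3 at -0.06 ± 0.01 (adjusted p = 0.00621).

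After PLN, the largest positive slopes belonged to CLIP4 (0.33 ± 0.04), the small heat shock protein gene HSPB6 (0.30 ± 0.04), LPL, LIPE, MYO5B (0.28 ± 0.06), PDLIM1 (0.27 ± 0.04), DDAH1 (0.27 ± 0.03, adjusted p = 2.45e-09), AKR1CL1 (0.25 ± 0.06) and TRNP1 (0.25 ± 0.04). The largest negative slopes belonged to NANOS1 (-0.27 ± 0.06, adjusted p = 0.00546), PTX3 (-0.25 ± 0.07), CD93 (-0.20 ± 0.05), BPGM (-0.17 ± 0.04), RMND5A (-0.15 ± 0.03), GPRC5B (-0.15 ± 0.03), CNRIP1 (-0.15 ± 0.03), DICER1 (-0.14 ± 0.05), NAA50 (-0.13 ± 0.03) and AP2B1 (-0.13 ± 0.04). In total 555 of 11986 probe sets passed, 332 higher and 223 lower with the score. Most calls in both directions were lost without pig 72 (90 higher and 33 lower), without the 2 extreme pigs (77 and 18), in odd-numbered pigs (32 and 3) and in even-numbered pigs (89 and 19). By 1 probe set per gene, 171 of 4919 genes were higher and 108 lower. None of 24 genes with several such probe sets had opposite signs.

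Of 21 fatty acid oxidation genes 11 were higher, none lower and 10 did not pass (16 higher when adjusted over the list alone). This set moved up by camera (adjusted p = 5.97e-17), also with an estimated correlation (adjusted p = 0.00838). Of 32 oxidative phosphorylation genes 14 were higher and 18 did not pass (27 adjusted over the list alone, camera adjusted p = 1.85e-22, adjusted p = 0.0605 with an estimated correlation). Of 19 TCA cycle genes 8 were higher, such as IDH2 (0.10 ± 0.02), and 11 did not pass (14 adjusted over the list alone, camera adjusted p = 7.77e-11, adjusted p = 0.0763 with an estimated correlation). PGAM2 and ENO3 were lower of 11 glycolysis genes (4 adjusted over the list alone, camera adjusted p = 0.000297, adjusted p = 0.175 with an estimated correlation). GYG1 and PYGM were lower of 10 glycogen genes (4 adjusted over the list alone, camera adjusted p = 0.00416, adjusted p = 0.22 with an estimated correlation). TPM1, TNNT3 and TNNI2 were lower of 9 fast fibre genes (3 adjusted over the list alone, camera adjusted p = 0.000389, adjusted p = 0.245 with an estimated correlation).

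RPL7 and RPL27 were lower of 31 ribosomal protein genes (5 adjusted over the list alone, camera adjusted p = 3.96e-05, adjusted p = 0.368 with an estimated correlation). PSMB5 and PSMB6 were lower of 25 proteasome genes (3 adjusted over the list alone, camera adjusted p = 6.88e-05, adjusted p = 0.368 with an estimated correlation). No interferon response gene passed (2 of 10 higher adjusted over the list alone, camera adjusted p = 0.000125, adjusted p = 0.22 with an estimated correlation). Calcium handling genes had PLN higher of 4 (1 adjusted over the list alone), with a median slope of -0.03 and a mean of 0.08. Among the rest, SLC25A1 (lipogenesis), LIPE (triglyceride list) and FABP3 (meat quality candidates) were higher and VEGFA (hypoxia) lower, each the only member of its list to pass, also adjusted over the list alone. No gene of the adipocyte, extracellular matrix, immediate early, heat shock, proteolysis, cholesterol, macrophage, myogenic, circadian, smooth muscle, nerve or red blood cell lists passed. When adjusted over the list alone, 1 smooth muscle gene did. Beside these, the endothelial cadherin gene CDH5 was higher (0.15 ± 0.03, adjusted p = 0.00186) of 8 endothelial genes (5 adjusted over the list alone, camera adjusted p = 9.6e-05, adjusted p = 0.0763 with an estimated correlation). The 3' minus 5' difference of control probe sets, a measure of RNA integrity, correlated with the slow fibre score at r = 0.254 (permutation p = 0.0518, adjusted p = 0.155, rho = 0.281, p = 0.0315, adjusted p = 0.0945, r = 0.203 without 2 pigs, 15 correlations in the family). The count of 555 fell to 123 without pig 72 and to 95 without the 2 most extreme pigs, where 5 of 21 fatty acid oxidation, 5 of 32 oxidative phosphorylation and 1 of 19 TCA cycle genes were higher. Of the genes with the 10 largest negative slopes 2 were then still called, and of those with the 10 largest positive slopes 8. These genes had been chosen to keep their sign and an unadjusted p under 0.05 without the same 2 pigs, which favours them here. The count of 555 was 929 (468 higher and 461 lower) with the first principal component and 95 with the other 3 scores as covariates, where 5 of the 10 largest positive and 3 of the 10 largest negative slopes were still called. The count was 334 on ranks of the score, 35 in odd-numbered and 108 in even-numbered pigs.

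Which genes followed the oxidative phosphorylation score was asked to describe mitochondrial expression. TCA cycle and fatty acid oxidation genes were higher in pigs with a higher score. ETFA, a subunit of the electron transfer flavoprotein, was higher by 0.13 ± 0.01 log2 per SD of the score (SE, n = 59, limma adjusted p = 1.04e-13). IDH3B was higher by 0.12 ± 0.01 (3.79e-13), DLD by 0.14 ± 0.01 (1.36e-11), the trifunctional protein gene HADHB by 0.21 ± 0.02 (1.16e-09) and the fatty acid binding protein gene FABP3 by 0.24 ± 0.03 (1.33e-08). Of 9 slow fibre genes 7 were higher too, such as MYL3 (0.18 ± 0.04), TNNC1 (0.14 ± 0.02) and TNNT1 (0.11 ± 0.02), with adjusted p from 1.36e-05 to 0.000447. MSTN, which encodes the growth inhibitor myostatin, was lower (-0.24 ± 0.08, adjusted p = 0.0429).

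The largest positive slopes were those of the aspartate aminotransferase gene GOT1 (0.34 ± 0.05, adjusted p = 4.92e-07), the mitochondrial cyclophilin gene PPIF (0.32 ± 0.05), OXNAD1 (0.31 ± 0.05), TP53INP2 (0.31 ± 0.06), LPCAT3 (0.31 ± 0.06), ANKRD29 (0.30 ± 0.07), PKIB (0.29 ± 0.06), GDE1 (0.29 ± 0.04), the pantothenate kinase gene PANK1 (0.29 ± 0.05) and TRNP1 (0.28 ± 0.04). The largest negative slopes were those of PTX3 (-0.29 ± 0.07, adjusted p = 0.00409), STK26 (-0.28 ± 0.06), MID1IP1 (-0.24 ± 0.05), MSTN, CLU (-0.24 ± 0.06), SLC25A24 (-0.21 ± 0.05), MLLT3 (-0.21 ± 0.06), TCFL5 (-0.19 ± 0.04), VGLL4 (-0.18 ± 0.05) and STBD1 (-0.18 ± 0.05). In total 1185 of 11962 probe sets passed, 834 higher and 351 lower. With arrays re-centred on their medians 1029 were higher and 256 lower. The split was 949 and 591 without pig 36, 562 and 142 without pig 72, 118 and 13 in odd-numbered pigs and 564 and 132 in even-numbered pigs. By 1 probe set per gene, 451 of 4896 genes were higher and 154 lower. None of 44 genes with several such probe sets had opposite signs.

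Of 19 TCA cycle genes 15 were higher, none lower and 4 did not pass (16 adjusted over the list alone). Of 21 fatty acid oxidation genes 15 were higher and 6 did not pass (18 adjusted over the list alone). Both sets moved up by camera (adjusted p = 8.11e-20 and 1.7e-16), also with an estimated correlation (adjusted p = 0.000274 and 0.000411). Of 9 slow fibre genes 7 were higher (7 adjusted over the list alone, camera adjusted p = 2.82e-05, adjusted p = 0.196 with an estimated correlation). RPL7, RPL15 and RPL13 were lower of 31 ribosomal protein genes (3 adjusted over the list alone, camera adjusted p = 2.82e-05, adjusted p = 0.468 with an estimated correlation). TNNT3 was lower of 9 fast fibre genes (3 adjusted over the list alone, camera adjusted p = 0.0235, adjusted p = 0.468 with an estimated correlation). COL5A1 was lower of 15 extracellular matrix genes (1 adjusted over the list alone, camera adjusted p = 0.0235, adjusted p = 0.506 with an estimated correlation).

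PGAM2 and ENO3 were lower of 11 glycolysis genes (3 adjusted over the list alone), and STBD1, PGM1 and GYG1 of 10 glycogen genes (5 lower and 2 higher adjusted over the list alone). PNPLA2, DGAT1 and AGPAT2 were higher of 10 triglyceride genes, SLC25A1 of 5 lipogenesis genes, HMGCS1 (0.14 ± 0.02) and SC5D of 9 cholesterol genes and IFIT2 of 10 interferon genes, all with unchanged counts over the list alone. MSTN and MYF5 were lower of 7 myogenic genes, CAPN2 of 15 proteolysis genes and BHLHE40 of 5 circadian genes, again with unchanged counts. In the calcium handling list PLN was higher (0.23 ± 0.06) and the ryanodine receptor gene RYR1 lower (-0.10 ± 0.03, adjusted p = 0.028), and these counts also held over the list alone. Of 15 meat quality candidates FABP3 was higher and RYR1 and MSTN were lower (2 higher and 2 lower adjusted over the list alone). No gene of the adipocyte, immediate early, heat shock, hypoxia, proteasome, macrophage, smooth muscle, nerve or red blood cell lists passed. Over its list alone 1 smooth muscle gene did. CDH5 was higher of 8 endothelial genes (2 adjusted over the list alone). The 3' minus 5' control difference correlated with the score at r = 0.291 (permutation p = 0.0261, adjusted p = 0.0979, rho = 0.321, p = 0.0128, adjusted p = 0.048, r = 0.294 without 2 pigs, 15 correlations in the family). The count of 1185 fell to 704 without pig 72, and it was 131 in the 27 odd-numbered and 696 in the 32 even-numbered pigs. Without the 2 extreme pigs 5 of the 10 genes with the largest negative slopes were still called, although all had been chosen to keep an unadjusted p under 0.05 there. With the other 3 scores as covariates TNNI1 and MYH7 turned sign, to -0.0027 and -0.0063. Both are members of the slow fibre score, which was among those covariates, so slopes near 0 were largely set in advance.

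Which genes followed the immediate early score was asked because the muscle was sampled at slaughter. The chemokine gene CXCL2 was higher by 0.66 ± 0.08 log2 per SD of the score (SE, n = 59, limma adjusted p = 9.63e-09), the striated muscle genes XIRP1 by 0.64 ± 0.09 (3.89e-07) and ANKRD1 by 0.55 ± 0.10 (0.000148). The growth arrest gene GADD45A was higher by 0.61 ± 0.11 (0.000126). Of 15 heat shock genes 9 were higher too, among them DNAJB1 (0.44 ± 0.10, adjusted p = 0.00242), DNAJA1 (0.29 ± 0.07, 0.00688), HSPB1 (0.23 ± 0.06, 0.00806) and BAG3 (0.20 ± 0.05, 0.0046). ADM, the gene of the vasodilator peptide adrenomedullin, was higher by 0.33 ± 0.05 (adjusted p = 3.39e-06) and the myogenic factor MYF6 by 0.30 ± 0.07 (adjusted p = 0.00233). MSTN was lower (-0.25 ± 0.08, adjusted p = 0.0281).

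The other largest positive slopes were those of RRAD (0.54 ± 0.09), HSPA6 (0.54 ± 0.15), THBS1 (0.53 ± 0.11), NR4A2 (0.52 ± 0.09) and SPECC1 (0.43 ± 0.09). The largest negative slopes were those of RIPOR2 (-0.39 ± 0.11, adjusted p = 0.0137), MSS51 (-0.38 ± 0.10), PPP1R3B (-0.35 ± 0.10), ARPP21 (-0.29 ± 0.07), MYLIP (-0.28 ± 0.06), ANKRD44 (-0.27 ± 0.09), MSTN, PTER (-0.25 ± 0.07), RHOBTB1 (-0.22 ± 0.06) and MLF1 (-0.22 ± 0.06). In total 1889 of 11984 probe sets passed, 949 higher and 940 lower. The balance turned with the scaling, to 789 higher and 1036 lower with quantile normalisation and to 1036 higher and 813 lower with arrays re-centred on their medians. By 1 probe set per gene, 409 of 4914 genes were higher and 392 lower. Of 80 genes with several such probe sets 3 had opposite signs (PABPN1, SAR1A and VEGFA, the former pair named after their values were seen).

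Of 15 heat shock genes 9 were higher, none lower and 6 did not pass (15 adjusted over the list alone, camera adjusted p = 8.31e-08, adjusted p = 0.864 with an estimated correlation). PSMD8, PSMA5 and PSMA1 were higher of 25 proteasome genes (3 adjusted over the list alone, camera adjusted p = 0.00597, adjusted p = 0.864 with an estimated correlation). In the hypoxia list ADM was higher and VEGFA lower of 6 (3 and 2 adjusted over the list alone). ABHD5 and LPIN1 were higher of 10 triglyceride genes, PDK4 of 21 fatty acid oxidation genes and the clock gene PER1 (0.18 ± 0.04) of 5 circadian genes, with unchanged counts over the list alone. FOXO1 and GABARAPL1 were higher of 15 proteolysis genes (1 over the list alone) and TIMP1 of 15 extracellular matrix genes (0 over the list alone). HK1 was higher and PFKM and PGK1 lower of 11 glycolysis genes. PGM1 and PHKB were lower of 10 glycogen genes, IDH3G of 19 TCA cycle genes and MYOZ1 of 9 fast fibre genes, and all 4 lists had unchanged counts over the list alone. MYF6 was higher and MSTN lower of 7 myogenic genes, and PDK4 higher and MSTN lower of 15 meat quality candidates, also over each list alone. No gene of the adipocyte, lipogenesis, oxidative phosphorylation, slow fibre, calcium handling, ribosomal, cholesterol, macrophage, interferon, endothelial, smooth muscle, nerve or red blood cell lists passed. The count of 1889 fell to 774 without pig 36, to 1057 without pig 37 and to 225 without the 2 most extreme pigs, where 1 of 15 heat shock genes was higher. Of the genes with the 10 largest negative slopes 2 were then still called, and of those with the 10 largest positive slopes 8. Their choice had already required the same sign and an unadjusted p under 0.05 without those 2 pigs, which favours them here. The count was 32 in odd-numbered pigs, 1308 in even-numbered pigs and 1157 on ranks of the score. The first principal component of probe sets in no list correlated with this score at r = 0.542 (permutation p = 2e-05, adjusted p = 0.00015, rho = 0.454, p = 0.00039, adjusted p = 0.00195, r = 0.432 without 2 pigs, 15 correlations in the family). The component also followed the heat shock score (r = 0.851), so as a covariate it may take out heat shock expression itself. With the component as a covariate the count was 77, 63 higher and 14 lower, with 0 heat shock genes called. Of the 10 largest positive slopes 4 were then called. Of the 10 largest negative slopes 0 were called and 6 kept their sign, while MSTN (0.051), PPP1R3B (0.062), ANKRD44 (0.027) and RHOBTB1 (0.052) turned positive. BAG3 (-0.0051) and DNAJA1 (-0.028) turned negative.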

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

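The alternatives were listed before the data were examined, except the EIF1AY level as a covariate, which was chosen after seeing the data. No paired analysis was possible because the labels give 1 group. For each change below the cause was not tested. Of 60 counts from 15 planned or added regression alternatives, 42 stayed within 1.5 times and 18 moved. In odd-numbered pigs 6, 35, 131 and 32 probe sets followed the adipocyte, slow fibre, oxidative phosphorylation and immediate early scores, and in even-numbered pigs 351, 108, 696 and 1308. With the first principal component as covariate 350, 929 and 77 followed the adipocyte, slow fibre and immediate early scores, and with the other 3 scores 1015 and 95 followed the adipocyte and slow fibre scores. Without the 2 most extreme pigs 95 and 225, and on ranks 334 and 1157, followed the slow fibre and immediate early scores. The adipocyte count was 1095 among the brightest 6000 probe sets and 682 with all named members. With the EIF1AY level as covariate the 4 counts were 1872, 568, 1160 and 1439. With 1 pig left out they ran from 1323 to 2335, 123 to 606 (lowest without pig 72), 704 to 1540 (lowest without pig 72) and 774 to 2254 (lowest without pig 36, then 1057 without pig 37). Among the brightest 6000 probe sets 12 genes had an SD of at least 1. Between 16 and 20 lists passed as coordinated.

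Of 240 alternative correlations 200 kept direction and side of the threshold. In odd-numbered pigs adipocyte with lipogenesis (0.298) and with extracellular matrix (0.401), lipogenesis with cholesterol (0.140), oxidative phosphorylation with glycolysis (-0.458) and with ribosomal proteins (-0.220), and immediate early with heat shock (0.273) and with proteolysis (0.357) no longer passed. There slow fibre with calcium handling turned to -0.028. In even-numbered pigs slow with fast fibre (-0.383), oxidative phosphorylation with glycolysis (-0.206) and immediate early with proteolysis (0.227) did not pass. There immediate early with circadian clock turned to -0.147. Without 2 pigs lipogenesis with cholesterol (0.278), slow with fast fibre (-0.209), oxidative phosphorylation with glycolysis (-0.163) and with ribosomal proteins (-0.295), and immediate early with proteolysis (0.250) did not pass. By rho, slow with fast fibre (-0.258) and oxidative phosphorylation with glycolysis (-0.182) did not pass. With the first principal component of each list as score, adipocyte with triglyceride (-0.267), slow fibre with calcium handling (-0.672) and immediate early with circadian clock (-0.076) turned negative. Of these slow fibre with calcium handling then passed (adjusted p = 2.86e-05), but the sign of a component is arbitrary where a list's genes do not vary together, as in calcium handling (median r = -0.058). Adipocyte with macrophage (0.384) and immediate early with hypoxia (0.560) also passed, and oxidative phosphorylation with glycolysis (-0.256) did not. With the mean of all probe sets immediate early with hypoxia passed (0.456), and oxidative phosphorylation with glycolysis (-0.257) and immediate early with proteolysis (0.280) did not. With all named members lipogenesis with cholesterol did not (0.218). With quantile normalisation oxidative phosphorylation with glycolysis (-0.270) and immediate early with proteolysis (0.262) did not, and with re-centred arrays oxidative phosphorylation with glycolysis (-0.210) and with ribosomal proteins (-0.147) did not. Given the first principal component of probe sets in no list, adipocyte with triglyceride (0.286) and immediate early with circadian clock (0.374) passed, oxidative phosphorylation with glycolysis (-0.268) and immediate early with proteolysis (0.114) did not, and immediate early with heat shock turned to -0.077. That component itself followed the heat shock score (r = 0.851). Given the 3' minus 5' difference, oxidative phosphorylation with glycolysis (-0.245) and immediate early with proteolysis (0.254) did not pass. Given EIF1AY no call changed. With 1 pig left out, calls changed for slow with fast fibre (-0.462 to -0.243, pig 72), oxidative phosphorylation with glycolysis (-0.382 to -0.106, 14 pigs), immediate early with proteolysis (0.255 to 0.349, 13 pigs) and with hypoxia (0.208 to 0.356, pigs 40 and 72).

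Of 7117 alternative slopes of named genes 6363 kept the side of the threshold, and those among them that had passed kept their direction. Turns of sign were not counted for slopes that had not passed. Another 710 no longer passed, 22 newly passed and 22 that had passed turned sign. With the first principal component as covariate the slopes that turned were, on the adipocyte score, ABHD5 0.0033, PSMA5 0.0056, FBXL4 -0.034, PPP1R3B -0.022 and GADD45A 0.039. On the immediate early score they were ABHD5 -0.044, HK1 -0.0027, PGK1 0.0006, BAG3 -0.0051, DNAJA1 -0.028, HSPB8 -0.0068, CRYAB -0.0031, PSMD8 -0.0056, PSMA5 -0.025, PSMA1 -0.022, MSTN 0.051, PPP1R3B 0.062, ANKRD44 0.027 and RHOBTB1 0.052. The component itself followed the heat shock score (r = 0.851), so it may take out the expression of BAG3, DNAJA1, HSPB8 and CRYAB. With the other 3 scores TNNI1 (-0.0027) and MYH7 (-0.0063) turned on the oxidative phosphorylation score, and in odd-numbered pigs PFKM (0.0011) on the immediate early score. TNNI1 and MYH7 are members of the slow fibre score, which was among those covariates, so their slopes near 0 were largely set in advance. Signal near background was not separable from low expression in the deposited values, so the median filter is the only limit set on dim genes.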

Other observations

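The relations of single genes with scores, the tests on the first principal component and the comparison of extracellular matrix with endothelial genes were chosen only after the results had been seen, and so were the counts over reordered scores. The bounds for the CXCL9 test were set before its result was seen. CXCL9 correlated with GBP1 at r = 0.955 (n = 59, permutation p = 1e-05, adjusted p = 3e-05 over 9 relations, rho = 0.904, p = 1e-05, adjusted p = 2.25e-05, r = 0.950 without 2 pigs). It correlated with the macrophage and leukocyte score at r = 0.637 (p = 1e-05, adjusted p = 3e-05, rho = 0.609, p = 1e-05, adjusted p = 2.25e-05, r = 0.602 without 2 pigs). SPP1 correlated with the macrophage score at r = 0.5004 (permutation p = 4e-05, adjusted p = 9e-05, rho = 0.496, p = 8e-05, adjusted p = 0.000144, r = 0.499 without 2 pigs). GPNMB, which macrophages express, correlated with it at r = 0.418 (permutation p = 0.001, adjusted p = 0.00129, rho = 0.549, p = 1e-05, adjusted p = 2.25e-05, r = 0.359 without 2 pigs). SPP1 and GPNMB gave r = 0.311 (permutation p = 0.016, adjusted p = 0.016, rho = 0.429, p = 0.0008, adjusted p = 0.0009, r = 0.245 without 2 pigs). The interferon and macrophage scores gave r = 0.398 (permutation p = 0.00196, adjusted p = 0.0022, rho = 0.348, p = 0.00711, adjusted p = 0.00711, r = 0.411 without 2 pigs). The adipocyte and heat shock scores were related at r = -0.474 (permutation p = 0.00012, adjusted p = 0.00018, rho = -0.454, p = 0.00039, adjusted p = 0.000585, r = -0.519 without 2 pigs). A p of 1e-05 is the smallest that the resamples can give.

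EIF1AY lay between 3.05 and 3.52 in 33 pigs and between 9.97 and 10.56 in 26 pigs. OCA2 lay at or below 5.79 in 13 pigs and at or above 8.08 in 46 pigs, with a gap of 2.29. PON3 lay at or below 6.53 in 38 pigs and at or above 7.54 in 21 pigs. The labels give no group for these pigs, and no relation of EIF1AY or OCA2 with another gene is reported.

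The 4 counts of probe sets that followed a score were higher than those from random orders of the pigs. Only 1 of 100 orders, the observed one, gave as many calls for each score. The observed and highest other counts were 1893 and 6 for the adipocyte score, 555 and 22 for slow fibre, 1185 and 34 for oxidative phosphorylation, and 1889 and 1 for immediate early. Each score was formed from the same arrays as the probe sets, so any variation shared across an array can give such counts. Reordering the pigs therefore cannot tell what the probe sets followed.

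The first principal component of probe sets in no list followed the heat shock score at r = 0.851 (n = 59, 95% interval 0.768 to 0.911, permutation p = 1e-05, adjusted p = 3e-05, rho = 0.850, p = 1e-05, adjusted p = 2.25e-05, r = 0.831 without 2 pigs). Unnamed probe sets and unlisted stress genes such as HSPA6 stayed in the component, so it is not independent of heat shock expression. As a covariate it may therefore take out heat shock expression itself. RNA degradation would need a correlation of at least 0.5 in size with the 3' minus 5' control difference, a bound set after results had been seen. The value was -0.092 (95% interval -0.250 to 0.163). This difference averages standardised values of GAPDH, actin and EF1A, whose SDs were 0.051, 0.282 and 0.395 log2. GAPDH thus varied little but counts as much as the others. The value argues against degradation only as far as these controls record it, and degradation otherwise stays open. Hybridisation strength would need a correlation of the same size with the hybridisation controls, and the value was -0.180 (-0.418 to 0.084). These controls were read after quantile normalisation, which evens out strength between arrays. The value therefore cannot tell whether strength differed before that step. The same controls gave r = -0.236 (-0.425 to -0.010, permutation p = 0.072, adjusted p = 0.18 over 15 relations, rho = -0.229, p = 0.081, adjusted p = 0.203, r = -0.286 without 2 pigs) with the heat shock score. A contribution of hybridisation strength stays open. Unrecorded differences in handling, batch or time to freezing may underlie the component and stay open, since the labels give none of them, and no biological explanation was tested.

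Extracellular matrix genes followed the adipocyte score. A lower share of muscle fibres in some samples may raise adipocyte, matrix and endothelial genes alike. The correlation of the adipocyte score with the matrix score exceeded that with the endothelial score by 0.150 (95% interval -0.204 to 0.445), which leaves this open, as does the interval of -0.073 to 0.361 for the matrix and endothelial scores (r = 0.144). The second condition was added after the former value had been seen. The labels used here give no biological factor that differs between these pigs, and no biological explanation was tested.

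CXCL9 followed the interferon response genes without GBP1 at r = 0.515 (n = 59, permutation p = 6e-05, adjusted p = 0.000108, rho = 0.437, p = 0.00052, adjusted p = 0.000669, r = 0.452 without 2 pigs). More leukocytes in some samples could raise both. Given the macrophage and leukocyte score, the partial correlation was 0.413 (95% interval 0.141 to 0.654), and its interval holds the preset bound of 0.3, so this explanation stays open. The labels used here give no biological factor that differs between these pigs, and no biological explanation was tested.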
